A study of Chlamydomonas reinhardtii with 9 samples.

How the data were processed

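RNA was measured in 9 cultures of wild-type Chlamydomonas reinhardtii, strain CPCC11, exposed for 2 h to no added mercury, to 0.05 nM or to 0.5 nM methylmercury, with 3 replicates per group. Per the labels' protocols, RNA was extracted with TRI Reagent after breaking frozen pellets with glass beads, and libraries were made with a stranded Illumina mRNA kit. An Illumina HiSeq instrument is named in the labels of the 0.05 nM samples only. The sequencer of the other samples is not given in the sources used here. The labels of the 0.05 nM samples also describe the source in other words, so a separate submission cannot be told apart from the dose.

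The authors deposited raw read counts per gene for each library. Per the submitters' processing notes, reads were aligned with TopHat2 and counted with HTSeq. Versions, genome build, annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping genes on opposite strands may not be separated. The count files end with HTSeq's categories of unassigned reads, which were kept out of library sizes and tests. Of the assigned, ambiguous and outside reads together, reads outside gene models made up 1.02% to 1.24% and ambiguous reads 0.264% to 0.331%. The other unassigned categories were left out of that total. Alignments at more than one place were not assigned, so genes with near-identical copies are measured by their unique parts. The authors' deposited table of the series repeats the counts (9 of 9 count columns equal the separate files), and adds CPM values rounded to whole numbers, which lie within 0.5 of count divided by total. These rounded values, a score in whole numbers deposited by the authors, were not tested. The table also holds the authors' own signed fold ratio, p-values and FDR-corrected p-values for each dose against control, which the authors deposited without sample values and which are quoted as theirs.

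Of the 17737 identifiers, 12263 carry the Cre numbering and 5474 are g numbers. A RefSeq gene table of the reference assembly, version 5.5, matched 11713 of them by locus tag, but it lists 0 symbols other than the locus tag. It was used only for which loci are neighbours, and no coordinates are printed. Since neither the files nor that table pair identifiers with names, genes are given by identifier. Before the data were examined, 26 gene lists were fixed by symbol or product pattern, with locus numbers recalled from the version 5 numbering to be used for membership where no names could be had. That was the case for all lists. Locus numbers had been fixed for 13 lists, of which 11 had at least 5 tested loci and were tested. The lists for flagella and motility and for ABC transporters had 3 and 1 tested loci, and the other 13 lists gave no result. The recalled numbers could not be checked against a table of names, and some were absent from the count files. Present were 22 of 35 photosystem, 13 of 16 metal, 8 of 11 glutathione and 7 of 9 nitrogen numbers. For the carbon concentrating mechanism 11 of 12 were present, and for heat shock 8 of 9. All 5 photoprotection, 13 chlorophyll and 12 antioxidant numbers were present. As a rough check, the median expression rank of the photosystem list lay at percentile 98.98 and that of the Calvin-Benson list at 98.95, and 0 of 10000 random lists of the same size reached either. By expression the lists for glutathione (73.8) and metal transport (69.3) stood apart less, with 567 and 703 of 10000 random lists as high.

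Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr on the groups, libraries were scaled by TMM, and a quasi-likelihood model with robust estimation was fitted to all 9 libraries with group as the only term, which left 6 residual degrees of freedom. Each dose was tested against control, the doses against each other, and both dose terms together, with Benjamini-Hochberg adjustment over 14778 genes and a threshold of 0.05, two-sided. Standard errors were derived from the fold change and the F statistic. Gene lists were tested with limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 11 lists. Identifiers printed were, per comparison, up to 2 higher and 2 lower with the largest change among genes past the threshold with a mean of at least 1 CPM and no overlap between the groups. The design had called for named genes of the lists as well, which had no names to print.

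Depth was 15138888 to 20433375 assigned counts per library. On simulated counts with 200 changed genes, pooled over 5 simulations for 0.5 nM against control, the test recovered 16.7% of genes changed by 0.5 on the log2 scale, 74.3% of those changed by 1 and 93.9% of those changed by 2, and 5.54% of its calls were false. For 0.05 nM against control 7.83% of calls were false, and for 0.5 nM against 0.05 nM 6.61%, slightly above the nominal level. DESeq2 gave 12.6% to 13.5%. With so few changed genes the adjustment is stricter than in the comparisons with control, where far more genes passed. These recoveries therefore apply to a comparison in which few genes change. The simulated libraries were drawn independently of each other and fitted with group as the only term.

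Libraries were compared with each other before averaging. No pair of replicates agreed within sampling noise (lowest chi-square per degree of freedom 4.55), so each counts as 1 replicate. The series design text calls them biological replicates. The labels number the replicates 1 to 3 in each group but do not say what a number shares. Deviations of same-numbered libraries from their group means correlated at 0.104 to 0.63 in all pairs, against -0.491 to 0.371 for different numbers. Of the 9 libraries, 7 correlated best with a library of their own number. The correlations were clearest for replicate 1 (lowest 0.57). Control replicate 3 correlated more with the treated replicate 2 libraries (0.337 and 0.371) than with those of its own number (0.104 and 0.21). By the rule fixed for this check the numbers were taken to pair the samples, and a fit with the replicate block is given beside a gene count or a list where it changes a call or a count, but was not made for the overlap of the doses.

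Alternatives planned before the data were examined were RLE size factors, no low-count filter, a stricter filter (at least 1 CPM in 3 libraries and a mean count of 10), DESeq2, the replicate block, a log2 change of at least 1, fits on only the groups compared, an estimated correlation and limma's fry for the lists, and leaving out each library. Library totals without composition correction and replicates 2 and 3 only were added after seeing the data. Chance overlap of the doses was simulated with 20 sets of unchanged groups.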

Results

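Transcript levels were measured by RNA sequencing in wild-type Chlamydomonas reinhardtii, a unicellular green alga, of strain CPCC11. Cells were kept for 2 h in an artificial freshwater medium without mercury or with methylmercury (MeHg), an organic form of mercury that binds thiol groups. Methylmercury was given at 0.05 nM or at 0.5 nM. The 9 libraries formed 3 groups of 3 biological replicates. Between 15138888 and 20433375 reads per library were assigned to genes, with group means of 17463000 ± 2650000 in the controls, 17959000 ± 1111000 at 0.05 nM and 17765000 ± 2647000 at 0.5 nM (SD, n = 3 each). Of the gene identifiers in the deposited tables, 14778 had enough counts to be tested.

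The treated libraries lay apart from the controls. CPM are counts scaled by the library total after TMM correction for composition. The Spearman correlation of log2 CPM was 0.983 to 0.995 between replicates of a group and 0.98 to 0.995 between libraries of the 2 doses. Between control and treated libraries it was 0.929 to 0.966. The first principal component held 71.3% of the variance and separated the 3 controls from the 6 treated libraries. The second held 12.4% and set the replicate 1 library of each group on one side. The 10 genes with the most reads took 7.09% ± 0.247 of assigned reads in the controls, 5.87% ± 0.174 at 0.05 nM and 6.25% ± 0.736 at 0.5 nM (SD, n = 3 each). Alignments at more than one place, which were not assigned to genes, came to 31.6% ± 10.5 of the assigned count in the controls, with 43.7% in control replicate 3, and to 19.99% ± 1.45 at 0.05 nM and 22.1% ± 1.16 at 0.5 nM (SD, n = 3 each).

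At 0.05 nM against control, which asks for the response to the lower dose, loci of the carbon concentrating mechanism rose together. This set of transporters and carbonic anhydrases raises the carbon dioxide level around Rubisco when inorganic carbon is scarce. All 11 tested loci rose, by 0.51 to 3.92 on the log2 scale, with a median of 2.18 or 4.53-fold. The 5 photoprotection loci, for antenna-related proteins that help dissipate excess absorbed light, all rose, by 0.95 to 2.34 with a median of 1.57. Of 8 loci for heat shock proteins and chaperones, which assist protein folding, 5 fell and none rose (7 with the replicate block), with a median of -0.67 over the 8. The count was 1 without 0.05 nM replicate 3, 3 without control replicate 1, control replicate 2 or 0.05 nM replicate 2, and 7 without 0.5 nM replicate 3. Of 7 nitrogen assimilation loci, 4 rose and none fell (5 with the block), with a median of 0.45.

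In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 7714 genes passed, 4015 of them higher and 3699 lower at 0.05 nM, or 4900 and 4500 with the replicate block. Changes of at least 1 on the log2 scale were found for 1345 higher and 1039 lower genes. The 3 treated libraries lay all above or all below the 3 controls for 60.1% of the genes tested, against 10% by chance. Scaling by library totals alone, chosen after seeing the data, shifted the median gene by 0.26 on the log2 scale and changed the split to 5905 higher and 2080 lower genes, so directions are relative to the composition-corrected scale.

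Limma's camera test with a preset correlation put the carbon concentrating mechanism list (adjusted p = 2.23e-05) and the photoprotection list (adjusted p = 0.00767) above the other genes at 0.05 nM. Both calls were lost with an estimated correlation (adjusted p = 0.564 for each). Heat shock (adjusted p = 0.0652) and nitrogen assimilation (adjusted p = 0.0652) did not pass, but did with the replicate number as a block (adjusted p = 0.0195 and 0.0377). With the block and an estimated correlation neither passed (adjusted p = 0.549 for each). Both also passed without a low-count filter (adjusted p = 0.0489 for each). The heat shock list passed without control replicate 3 too (adjusted p = 0.0496), within a range of 0.0195 to 0.564 over its alternatives, and for nitrogen assimilation camera's alternatives ran from 0.0377 to 0.564. With library totals alone, 1 heat shock locus fell in place of 5, although the list passed camera's test (adjusted p = 0.0389). Adjusted over the list alone, 11 carbon concentrating mechanism, 5 photoprotection and 5 nitrogen loci rose and 6 heat shock loci fell. The files do not pair identifiers with gene names. The lists therefore rest on locus numbers recalled before the data were examined, which no table used here could check. The photoprotection and carbon concentrating lists also hold near-identical copies, whose reads may be lost or shared.

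The other lists changed less or in both directions at 0.05 nM, and none passed the camera test. Of 8 loci for glutathione, its transferases and sulfur assimilation, which supply the thiols that bind mercury, 4 fell and 1 rose, with a median of -0.26 (camera adjusted p = 0.413). Limma's fry, which tests a list alone and not against other genes, called this list lower (fry adjusted p = 0.00366). With the replicate block 2 rose. Of 12 antioxidant enzyme loci, 2 rose and 2 fell (adjusted p = 0.893), or 4 and 4 with the block. Of 12 metal transport loci, 2 rose and 3 fell (adjusted p = 0.683), or 3 and 4 with the block. Of 13 chlorophyll and heme synthesis loci, 3 rose and 3 fell (adjusted p = 0.683), or 4 and 4 with the block. Of 9 lipid metabolism loci, 2 rose and 2 fell (adjusted p = 0.855), or 2 and 3 with the block. Of 10 Calvin-Benson cycle loci, 2 rose (adjusted p = 0.683), or 3 with the block and 0 adjusted over the list alone. Of 21 loci for photosystems, antenna and electron transport, 1 fell (adjusted p = 0.208), or 4 with the block and 0 adjusted over the list alone. Adjusted over the list alone, the glutathione, antioxidant, metal, chlorophyll and lipid counts were as given. With 1 library left out, 0 to 1 glutathione, 0 to 2 antioxidant, 1 to 3 chlorophyll and 0 to 3 Calvin-Benson loci rose, and 1 to 4 antioxidant, 2 to 5 chlorophyll, 1 to 3 lipid and 0 to 4 photosystem loci fell. The medians of the photosystem (-0.13), chlorophyll (-0.14), metal (-0.11) and lipid (-0.16) lists turned positive with library totals alone, at 0.14, 0.12, 0.15 and 0.07, and that of the glutathione list came to 0.0023. The metal and lipid lists had positive means (0.08 and 0.12), and the antioxidant list had a positive median and mean (0.09 and 0.03) where camera pointed down.

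Among single identifiers at 0.05 nM, g4485 rose from 3.45 ± 0.818 to 55.4 ± 8.98 CPM (SD, n = 3 each), a log2 change of 4.02 ± 0.32 (SE; edgeR adjusted p = 6.39e-06). Cre03.g162800, a locus of the carbon concentrating mechanism list, rose from 1.05 ± 0.102 to 15.9 ± 2.72 CPM, by 3.92 ± 0.831 (edgeR adjusted p = 0.00528). That call was lost with replicates 2 and 3 alone, chosen after seeing the data (adjusted p = 0.104, in a range of 2.2e-08 to 0.104 over the alternatives). Cre13.g567400 fell from 15.3 ± 3.62 to 1.53 ± 0.229 CPM, a log2 change of -3.32 ± 0.202 (edgeR adjusted p = 1.34e-06). Cre03.g205500 fell from 5.13 ± 1.11 to 0.617 ± 0.0787 CPM, a log2 change of -3.04 ± 0.254 (edgeR adjusted p = 4.39e-06). All 3 treated libraries lay beyond all 3 controls for each of these identifiers, as the rule for choosing them required.

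**Figure D1:**
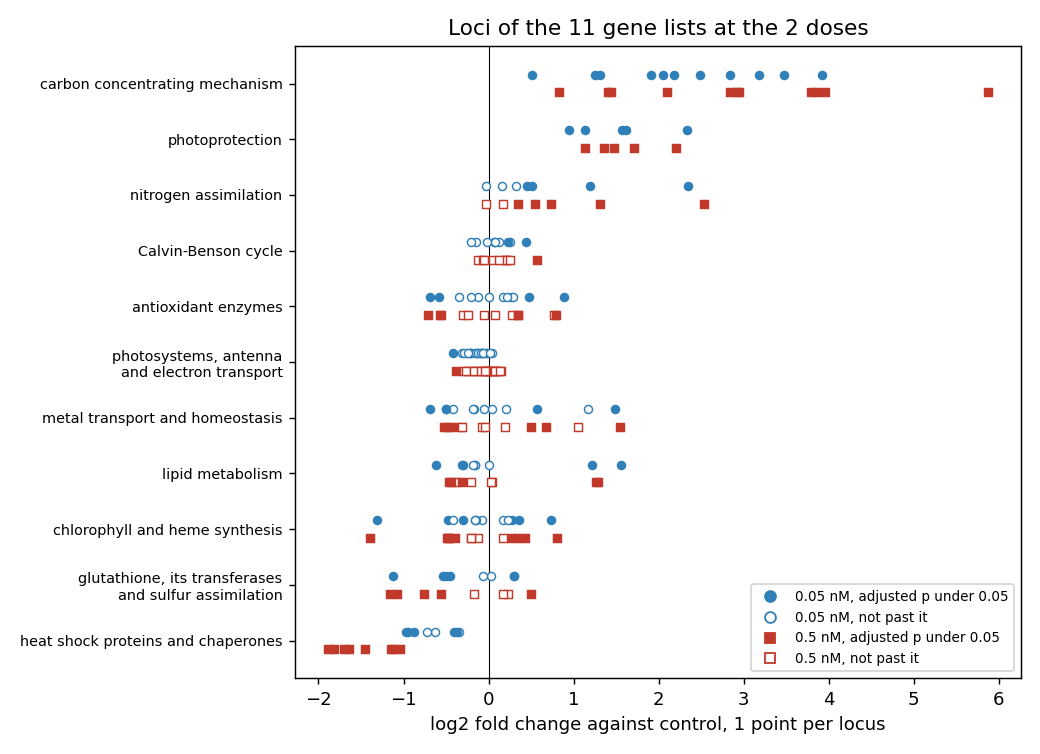
Log2 fold change against control (x axis) of each tested locus of the 11 gene lists (y axis), with circles for 0.05 nM and squares for 0.5 nM, filled where the adjusted p of edgeR's test was under 0.05. All 11 carbon concentrating mechanism loci and all 5 photoprotection loci lie above 0 at both doses, and all 8 heat shock loci lie below 0 at both.

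At 0.5 nM against control, which asks for the response to the higher dose, the carbon concentrating mechanism loci again rose and the heat shock loci fell. All 11 carbon concentrating mechanism loci rose, by 0.83 to 5.87 on the log2 scale, with a median of 2.93 or 7.60-fold. All 8 heat shock and chaperone loci fell, with log2 changes of -1.89 to -1.04 and a median of -1.55. All 5 photoprotection loci rose, by 1.13 to 2.21 with a median of 1.47, and 5 of 7 nitrogen assimilation loci rose, with a median of 0.54.

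In edgeR's test 8905 genes passed at 0.5 nM, 4671 of them higher and 4234 lower, or 5427 and 4853 with the replicate block, and 1881 higher and 1507 lower genes changed by at least 1 on the log2 scale. The 3 treated libraries lay all above or all below the 3 controls for 63.1% of genes, against 10% by chance. Library totals alone shifted the median gene by 0.29 on the log2 scale and gave 6707 higher and 2557 lower genes.

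Camera with a preset correlation called the carbon concentrating mechanism (adjusted p = 2.23e-05), photoprotection (adjusted p = 0.00971) and heat shock (adjusted p = 0.00168) lists at 0.5 nM. With an estimated correlation none of these calls held (adjusted p = 0.498, 0.498 and 0.376). Nitrogen assimilation did not pass (adjusted p = 0.0664), but did with the replicate block (adjusted p = 0.0412). Over camera's alternatives changed 1 at a time its adjusted p ran from 0.0412 to 0.376. With the block and an estimated correlation together it did not pass (adjusted p = 0.51). Adjusted over the list alone, the counts were 11 and 5 higher for the first lists, 8 lower for heat shock and 5 higher for nitrogen. With library totals alone, 7 of the 8 heat shock loci fell.

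Of the glutathione and sulfur loci, 4 fell and 1 rose at 0.5 nM, with a median of -0.36 (camera adjusted p = 0.425), and 3 rose with the block. Tested alone with fry, this list was called lower (fry adjusted p = 0.000421). Of the antioxidant loci, 2 rose and 3 fell (adjusted p = 0.764), or 5 and 5 with the block. Of the chlorophyll and heme loci, 4 rose and 5 fell (adjusted p = 0.605), or 5 and 7 with the block. Of the metal transport loci, 3 rose and 4 fell (adjusted p = 0.894), or 4 and 4 with the block. Of the lipid loci, 2 rose and 3 fell (adjusted p = 0.764), or 2 and 4 with the block. In the Calvin-Benson cycle 1 locus rose (adjusted p = 0.605), or 2 with the block. In the photosystem list 1 locus fell (adjusted p = 0.605), or 4 with the block and 0 adjusted over the list alone. For the other lists the counts adjusted over the list alone were as given. With 1 library left out, 0 to 4 antioxidant and 2 to 4 chlorophyll loci rose, and 3 to 7 chlorophyll, 2 to 4 metal and 0 to 3 photosystem loci fell. The medians of the photosystem (-0.04), chlorophyll (-0.20), metal (-0.06) and lipid (-0.20) lists turned positive with library totals alone, at 0.25, 0.09, 0.23 and 0.09. The metal and lipid lists had positive means (0.15 and 0.09), and the antioxidant list had a positive median and mean (0.01 and 0.02) where camera pointed down.

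Cre03.g162800 rose from 1.05 ± 0.102 to 61.4 ± 56.8 CPM at 0.5 nM (SD, n = 3 each), a log2 change of 5.87 ± 0.812 (SE; edgeR adjusted p = 0.000458). Its counts at that dose ran from 539 to 1903, and the log2 change was 4.77 without 0.5 nM replicate 3, in a range of 4.77 to 6.22 over its alternatives. g4485 rose from 3.45 ± 0.818 to 77.3 ± 33.3 CPM, by 4.50 ± 0.323 (edgeR adjusted p = 1.81e-06). Cre08.g364550 fell from 79.9 ± 14.3 to 6.62 ± 1.54 CPM, a log2 change of -3.58 ± 0.216 (edgeR adjusted p = 5.6e-07). Cre03.g205500 fell from 5.13 ± 1.11 to 0.419 ± 0.146 CPM, a log2 change of -3.55 ± 0.269 (edgeR adjusted p = 1.25e-06). All 3 treated libraries lay beyond all 3 controls for each of these identifiers, as the rule for choosing them required.

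The doses moved largely overlapping sets of genes. Genes higher at both doses numbered 3698 and genes lower at both numbered 3477, and 1 gene was called in opposite directions. Of the 7175 genes called in the same direction, 76.4% had the larger change at 0.5 nM, and the median ratio of the log2 changes was 1.14. Independent lists of these sizes would share 1269 higher and 1060 lower genes. Across genes, which are not independent replicates, the log2 changes at the doses had a Pearson correlation of 0.958 and the same sign for 91.9%. Both comparisons use the same 3 controls, and 20 simulated sets of unchanged groups gave a mean correlation of 0.502 and the same sign for 66.6%. The covariance was 0.59, against 0.03 in those sets, a difference of 0.56. Genes called at both doses in those sets numbered 0 higher and 0.05 lower on average, and at most 0 and 1. No gene changed in those sets, so they cannot show what shared controls add where many genes change. The 3 controls cannot be split into parts of at least 2 libraries, so part of the excess in shared calls may come from the shared controls.

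**Figure D2:**
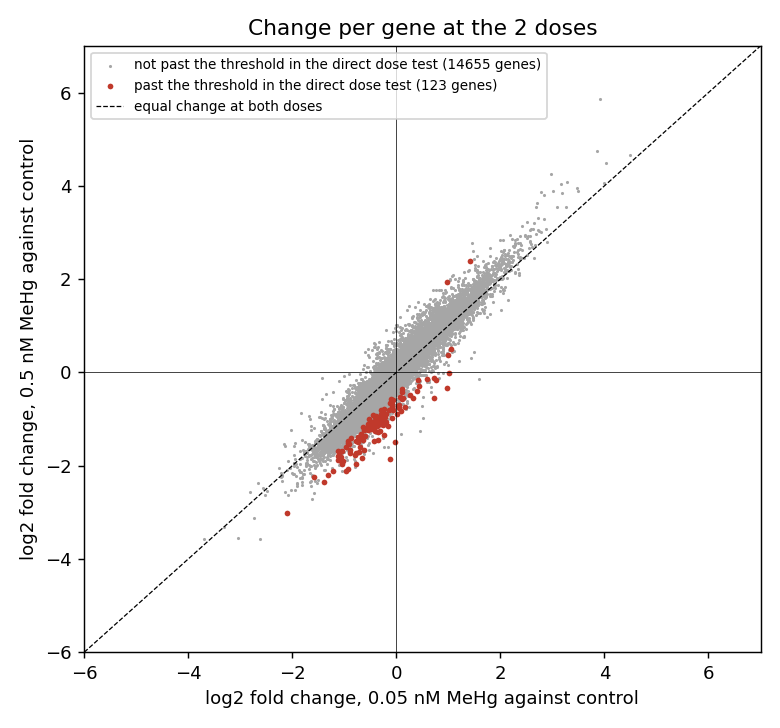
Log2 fold change against control at 0.5 nM (y axis) and at 0.05 nM (x axis), 1 point per tested gene, with the genes past the threshold in the direct test of the doses in red and equal change as a dashed line. Most points lie along the line, with a Pearson correlation of 0.958 across genes, and 121 of the red points were lower at 0.5 nM and 2 higher.

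The direct test of 0.5 nM against 0.05 nM asks which genes respond differently to the doses, and here the heat shock loci stood out. All 8 were lower at 0.5 nM, with log2 differences of -1.11 to -0.43 and a median of -0.80, and 2 of them passed the test. With 1 library left out 0 to 6 passed, and none did in the 7 cases in which no gene at all passed. Adjusted over the list alone 7 passed, as many as with the replicate block over all genes. The carbon concentrating mechanism loci were all higher, by 0.13 to 1.94 with a median of 0.49, but 0 passed, or 2 with the block. Without 0.5 nM replicate 3 that median was 0.21, and 10 of the 11 were higher.

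Relative to the control mean, the mean log2 CPM of the heat shock loci was -0.61 ± 0.127 at 0.05 nM and -1.46 ± 0.309 at 0.5 nM (SD, n = 3 each), without overlap between the doses. For the carbon concentrating mechanism loci the values were 2.28 ± 0.199 and 2.82 ± 0.538, and the libraries of the doses overlapped. Within the 3 replicate numbers the difference was 0.32 to 0.95, or 0.32 to 0.35 without 0.5 nM replicate 3. Camera with a preset correlation called the heat shock (adjusted p = 5.75e-08) and the carbon concentrating mechanism (adjusted p = 0.000541) lists in this comparison. Neither call held with an estimated correlation (adjusted p = 0.127 and 0.752).

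**Figure D3:**
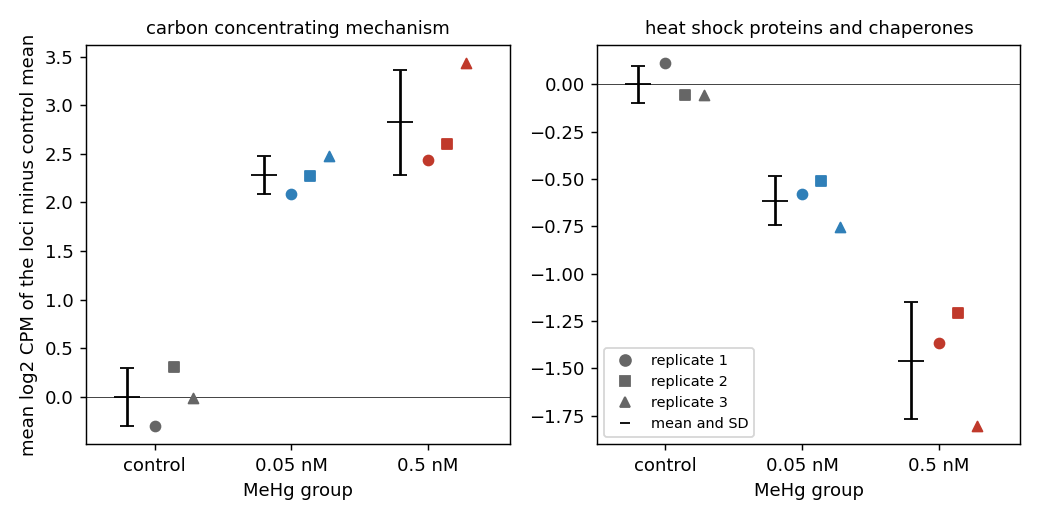
Mean log2 CPM of the listed loci minus the control mean (y axis) per library and group (x axis), with the carbon concentrating mechanism on the left and heat shock proteins on the right; symbols mark the replicate number and bars the mean and SD (n = 3). For heat shock, the 0.5 nM libraries run from -1.81 to -1.21 and the 0.05 nM libraries from -0.76 to -0.51.

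In edgeR's test between the doses 2 genes were higher and 121 lower at 0.5 nM, 0.832% of those tested, and 2002 had an unadjusted p under 0.05. Of the 121, 111 were also lower at 0.5 nM than in the controls. Library order separated the doses for 20.7% of genes, against 10% by chance. The count was not stable. With the replicate block it was 287 higher and 1041 lower genes, and DESeq2 gave 46 and 600. It was 0 in edgeR's test without any one of control replicates 2 and 3, 0.5 nM replicates 1 and 3 and the 3 libraries at 0.05 nM, where 1254 to 2020 genes had an unadjusted p under 0.05. It was 20 higher and 363 lower without control replicate 1, and 9 and 191 without 0.5 nM replicate 2.

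Cre17.g708750 was higher at 0.5 nM, at 342.6 ± 54.0 against 175 ± 26.0 CPM (SD, n = 3 each), a log2 difference of 0.97 ± 0.134 (SE; edgeR adjusted p = 0.0421). Cre12.g544450 was higher by 0.955 ± 0.17 (edgeR adjusted p = 0.043). Cre01.g019950 was lower, at 1.16 ± 0.658 against 3.99 ± 0.935 CPM, a log2 difference of -1.73 ± 0.33 (edgeR adjusted p = 0.0459). Cre07.g318850 was lower, at 15.9 ± 6.51 against 44.3 ± 8.12 CPM, a log2 difference of -1.47 ± 0.274 (edgeR adjusted p = 0.0484). All 3 libraries of one dose lay beyond all 3 of the other for each, as the rule for choosing them required. Each of these calls was lost in at least 9 of its alternatives, where the edgeR and DESeq2 adjusted p ran from 1.53e-07 to 0.233 for Cre17.g708750, from 0.000561 to 0.245 for Cre12.g544450, from 9.18e-05 to 0.245 for Cre01.g019950 and from 1.11e-06 to 0.304 for Cre07.g318850.

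The other lists did not pass camera's test between the doses. In the glutathione list 1 locus of 8 was lower (adjusted p = 0.584), or 0 to 1 with 1 library left out. No locus passed in the photoprotection (adjusted p = 0.607), nitrogen (adjusted p = 0.415), chlorophyll (adjusted p = 0.607), Calvin-Benson (adjusted p = 0.607), lipid (adjusted p = 0.607), antioxidant (adjusted p = 0.607), metal (adjusted p = 0.32) and photosystem (adjusted p = 0.32) lists. Adjusted over the list alone, 2 antioxidant loci and 1 glutathione locus were lower and 0 carbon concentrating mechanism loci passed, and with the block 2 antioxidant loci were lower and 1 metal locus was higher. The antioxidant list had a median of 0.02 and a mean of -0.01. The photosystem list passed without 0.5 nM replicate 1 (adjusted p = 0.0144), without 0.5 nM replicate 2 (adjusted p = 0.0434) and with replicates 2 and 3 alone (adjusted p = 0.0325), in a range of 0.0144 to 0.83 over its alternatives. Without 0.5 nM replicate 3 camera's direction turned from up to down, with a median of -0.07 in place of 0.09 (adjusted p = 0.301).

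Over the 3 groups together, edgeR's F test on both dose terms found 8440 genes that differed, 57.1% of those tested, or 10194 with the replicate block. The common biological coefficient of variation was 0.133.

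The authors' deposited table gave an adjusted p under 0.05 for 7315 genes at 0.05 nM, 3793 higher and 3522 lower. For 0.5 nM, the authors' deposited table gave 8615 genes, 4514 higher and 4101 lower. Of these, 7094 and 8370 genes in the authors' deposited table were also called here in the same direction. The log2 fold changes of the authors' deposited table had the same sign as those computed here for 99.96% and 99.99% of the genes tested here.

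Change also followed expression level. With the tested genes in 10 classes by mean over all 9 libraries, in the lowest class the median log2 change was 0.56 at 0.05 nM and 0.74 at 0.5 nM. In the highest class it was -0.26 and -0.34, but 0.01 and -0.05 with library totals alone, where the lowest class had 0.80 and 1.03. Of the called genes in the lowest class, 12.8% and 12.6% were lower at 0.05 nM and 0.5 nM, or 7.059% and 5.855% with library totals alone. In the highest class 86.8% and 88.3% were lower, or 57.7% and 60.7% with library totals alone.

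**Figure D4:**
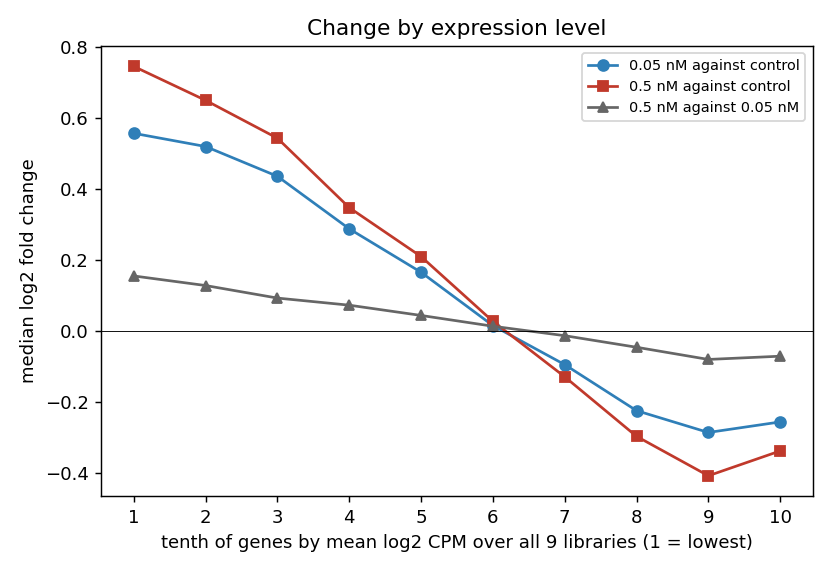
Median log2 fold change (y axis) in 10 equal classes of the tested genes ordered by mean log2 CPM over all 9 libraries (x axis, lowest first), for each of the 3 comparisons. Both doses run from positive medians in the lowest class (0.56 and 0.74) to negative ones in the highest (-0.26 and -0.34, or 0.01 and -0.05 with library totals alone).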

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

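The tests of the carbon concentrating mechanism list against a difference shared by both treated groups, and of the heat shock list against a single scale factor, were chosen after the results were seen. For both, the requirement that a bound be passed by more than 1 standard error was added later still, after the value for the carbon concentrating mechanism had been seen, and for that list it was later taken over pairs of replicates with the blocked fit, after the outcome over unpaired libraries had been seen. The comparison with all splits that part the replicate pairs was added after the first splits were seen. The other tests here were written before their values were seen.

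The direct test of the doses found 2 genes higher and 121 lower at 0.5 nM than at 0.05 nM, 0.832% of those tested. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split was the 1 split with as many genes, the highest other gave 0, and 4 of the 10 splits part all 3 pairs of replicate numbers as the real one does. The same holds for 0.05 nM against control (7714 genes, highest other 0) and for 0.5 nM against control (8905 genes, highest other 0). For the 3 groups together 1 of 100 splits, the real one, gave as many as 8440 genes, and the highest other gave 7473. The numbers were taken to pair the samples, so all 36 splits that part every pair were also fitted. The real one was the 1 split with as many genes, a share of 0.0278. This held both without the replicate block and with it (10194 genes, highest other 8633). The 3 others of these that kept the controls together gave 7312 to 7473 genes without the block, and the 32 that mixed controls with treated libraries gave at most 0. The result therefore rests on control against treated, which the real split shares with those 3 others. That is too many of the 36 for a share under 0.05, so chance was not excluded for control against treated.

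Camera placed the heat shock list lower at 0.5 nM than at 0.05 nM (adjusted p = 5.75e-08, median log2 difference -0.80), with 2 of 8 loci past edgeR's test, but the list did not pass with an estimated correlation (adjusted p = 0.127, in a range of 3.61e-09 to 0.127 over its alternatives). The list's call did not rest on 0.5 nM replicate 3 alone, since without it the adjusted p was 1.26e-07 and the median -0.71, although no single locus then passed. After removing the slope of 1.12 the loci lay at a median of -0.70, with 8 of 8 below 0, further down than that slope gives. The standard error over libraries of this difference, taken on their mean log2 CPM, was 0.197. The list was picked for its difference between the doses in the same libraries. The value is thus no separate evidence against a response in which every gene scales by a common factor. A dose-dependent loss of chaperone transcripts is a hypothesis that stays open, and so does a batch difference of the 0.05 nM samples.

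Camera placed the carbon concentrating mechanism list higher at 0.5 nM than at 0.05 nM (adjusted p = 0.000541, or 0.000235 with the replicate block). Over its alternatives changed 1 at a time the adjusted p ran from 4.6e-06 to 0.752. In edgeR's test 0 loci passed, or 2 with the block. The list did not pass with an estimated correlation (camera adjusted p = 0.752, or 0.825 with the block as well) or with fry (adjusted p = 0.432). Loci of this kind respond to inorganic carbon, so a difference between control and treated cultures could account for their rise without any action of the dose. If both treated groups shared it alike there would be no dose difference. The blocked median difference was 0.47, or 0.27 without 0.5 nM replicate 3 (blocked camera adjusted p = 0.0122). Differences in the loci's mean log2 CPM within the 3 pairs ran from 0.32 to 0.95, with a standard error of 0.206. The 2 pairs without 0.5 nM replicate 3 gave 0.32 and 0.35, with a standard error of 0.0135. Over unpaired libraries the standard errors were 0.331, and 0.14 without that replicate, beside medians of 0.49 and 0.21. After removing the slope of 1.12 over all genes, the loci lay at a median of 0.26, with 3 of 11 below 0. The bound was passed by more than 1 standard error only with the pairing. So few pairs cannot decide the question, and a difference shared alike stays open. A culture difference that itself differs between the treated groups, a batch difference of the 0.05 nM samples and a response to methylmercury stay open too.

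The share of reads outside gene models was taken of the assigned, ambiguous and outside reads together. It was 1.14% ± 0.0267 at 0.05 nM and 1.19% ± 0.0492 at 0.5 nM, against 1.08% ± 0.0475 in the controls (SD, n = 3 each). The share in 0.05 nM replicate 1 (1.1046%) lay below those in control replicates 2 and 3 (1.1057% and 1.108%). Within each of the 3 replicate numbers the share increased from control to 0.05 nM to 0.5 nM.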

How the results depend on the processing

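Library totals alone and replicates 2 and 3 alone were chosen after seeing the data. The counts for each dose against control stayed within 1.5 times under RLE, no filter, the stricter filter, DESeq2, the block, the fits on the groups compared and each library left out. They gave 3239 to 4074 higher and 3150 to 3765 lower genes at 0.05 nM and 4163 to 4704 and 3949 to 4260 at 0.5 nM when 1 library was left out. Requiring a log2 change of at least 1 left 1345 higher and 1039 lower genes at 0.05 nM, 1881 and 1507 at 0.5 nM, 0 and 13 between the doses, 3476 over the 3 groups, and 1248 higher and 957 lower at both doses. Fewer genes can meet that added condition. Library totals alone gave 2080 lower genes at 0.05 nM, 2557 at 0.5 nM, and 5586 higher and 1911 lower at both doses, with the median gene shifted up by 0.26 and 0.29 against control. Between the doses, where that shift was 0.04, they gave 0 higher and 0 lower between the doses in edgeR's test (1530 at an unadjusted p under 0.05, and 646 calls by DESeq2 on its own scale), for a reason not tested.

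Between the doses the counts moved under most settings, and the cause was not tested where none is given. They were 46 higher and 600 lower with DESeq2, 287 and 1041 with the replicate block, 3 higher without a filter, 53 lower with the 2 groups alone, and 0 and 1 with replicates 2 and 3 alone (2055 at an unadjusted p under 0.05). Leaving out 1 library gave 0 to 20 higher and 0 to 363 lower genes, more as well as fewer than with all 9 libraries. Gene lists past the threshold numbered 2, 3 and 2 for 0.05 nM, 0.5 nM and the dose difference, but 0, 0 and 0 with an estimated correlation, 5, 5 and 1 with fry, which tests the list alone and not against other genes, and 4 at 0.05 nM both with the block and without a low-count filter. The 5 lists called with fry at each dose were carbon concentrating mechanism, photoprotection, glutathione, heat shock and nitrogen assimilation. Replicates 2 and 3 alone gave 5 lists at 0.05 nM, where photosystems, heat shock and nitrogen assimilation also passed (adjusted p = 0.0499 for each). The block ended no call of a list or of a printed identifier. Of the genes called without it, 7711 of 7714 at 0.05 nM and 8898 of 8905 at 0.5 nM were also called with it. Of the values for single identifiers under alternatives, 139 stayed past the threshold in the same direction and 39 did not pass. Of the list values, 501 kept their side of the threshold, 19 passed anew and 8 no longer passed. No printed identifier and no list past its threshold changed direction. Directions of the other genes were not compared between settings. The majority of calls turned from higher to lower at 0.05 nM with RLE (3672 higher, 4045 lower) and DESeq2 (3420 and 4026) and without control replicate 3 (3450 and 3482). At 0.5 nM it did so with RLE (4330 and 4542) and DESeq2 (4123 and 4510). Several lists that did not pass changed camera's direction, among them photosystems at 0.5 nM with library totals alone. At this depth and with 3 libraries per group, changes of 0.5 on the log2 scale were recovered for 19.1% of simulated genes between the doses. The simulated libraries were not paired, few genes changed, and the fit had no block. Small dose differences are thus mostly out of reach of that fit where few genes change. The simulation does not cover the fit with the block, which called more genes.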

Other observations

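The tests of expression level and of neighbouring loci were written before their values were seen, although a first look ordered by control level had shown the trend itself, and the gene called in opposite directions was picked after its values were seen. The classes with library totals alone were also computed after the trend was seen, and the verdict on background was then made to hold for every scaling.

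All 3 tested loci of the flagella and motility list, too few for a list test, fell at both doses in edgeR's test, with log2 changes of -1.25 to -1.12 at 0.05 nM and -1.65 to -1.42 at 0.5 nM. They fell under library totals alone too, with -0.98 to -0.85 and -1.34 to -1.12. The 3 loci were abundant (means of 4021 to 7052 CPM), and the list's symbol pattern also covers tubulins. They need not be specific to flagella, so a fall of flagellar genes cannot be read from them. The 1 tested ABC transporter locus, which is also a carbon concentrating mechanism locus, rose by 2.48 and 2.93. The 1 gene called in opposite directions, Cre09.g413150, was higher at 0.05 nM by 0.44 ± 0.119 (SE; edgeR adjusted p = 0.00925) and lower at 0.5 nM, at -0.30 ± 0.12 (edgeR adjusted p = 0.0478).

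In the lowest of 10 classes by expression the median change was above 0 at both doses. Of its 1478 genes, 478 were called higher and 70 lower at 0.05 nM, and 644 and 93 at 0.5 nM. In the highest class the median was below 0 on the composition-corrected scale, but near 0 (0.01 and -0.05) with library totals alone. Background reads added to every gene in the treated libraries could raise low genes, but would leave almost no low gene lower. In the lowest of 5 classes of genes 13.6% of the calls at 0.5 nM were lower (220 of 1624, exact 95% interval 11.9% to 15.3%), which is more than background would leave, but 6.402% (5.34% to 7.6%) with library totals alone, so background cannot be told apart from other causes while the right scaling is not known. Regression to the mean from ordering genes by control level is argued against, since the gap between the lowest and the highest of 10 classes was 1.08 with genes ordered by the mean of all 9 libraries. A difference in RNA composition between the cultures and a transcriptional response stay open, and none was tested here.

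Neighbouring loci may change together. Log2 changes at 0.5 nM of 8265 adjacent pairs of tested loci had a Spearman correlation of 0.133 across pairs, above the highest of 1000 shuffled orders (0.0434; permutation p = 0.000999, the smallest they can give). The shuffled orders did not hold expression level, which the changes also followed. A like expression level of neighbours, adjacent duplicates, reads shared between overlapping genes and common regulation were not separated.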
